A study of Homo sapiens with 6 samples.

How the data were processed

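Small-RNA libraries were made from exosomes released by HCT116 cells, an established human colorectal carcinoma line. Per the labels' protocols, cells received either a control siRNA (siCTL) or an siRNA against PRDX3 (siPRDX3) by microporation, and were kept for 40 h. They were then moved to medium with nanoparticle-depleted serum for 24 h, after which exosomes were isolated with a commercial kit, exosomal RNA was extracted with a phenol-based reagent, and libraries were built with a small-RNA kit. The sample titles give 3 libraries per group. The series' design text ends with a sentence that names another siRNA and endothelial cells; it contradicts the titles and the cell line given for every sample, and the titles were followed. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

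The authors deposited 1 table per library, with 2588 mature miRNA entries and a value for each on a log2 scale. The submitters' processing notes name Bowtie2 and bedtools 2.25.0, with no role or order; the genome build, the miRNA annotation, any filter on the reads, the scaling between libraries and the way multiply mapped reads were treated are not given in the sources used here. The deposited log2 values were taken apart as log2(x + 1), where x is called a scaled CPM here. Within each library x lies on whole multiples of 1 step, which is the worth of a single read. Of the values of up to 100 reads, 100% came out whole within 0.1 read in each library. The step was 25.0, 20.0 and 7.98 scaled CPM in siCTL 1, 2 and 3, and 2.97, 7.09 and 6.72 in siPRDX3 1, 2 and 3. The deposited x summed to 1005190, 1616280 and 994749 in the siCTL libraries and to 686860, 684908 and 474714 in the siPRDX3 libraries, so the values are not plain CPM and a further scaling had been applied. Values have 3 decimals, so recovered reads of abundant miRNAs are approximate.

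Recovered reads summed to 40149, 80956 and 124732 in siCTL 1, 2 and 3, and to 230947, 96654 and 70678 in siPRDX3 1, 2 and 3. These are reads assigned to miRNA entries, not sequenced reads. A share of reads in a single library carries an exact 95% Clopper-Pearson interval, and a count of 0 allows a share of up to 3 reads of the total, which is 0.00747% in the smallest library and 0.00130% in the largest. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

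The design fixed before the data were examined planned a count-based test for raw counts, and limma on log2(value + 1) for normalized values. Because the deposited values are on a log2 scale, the limma test was the main one: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on the deposited log2 values of all 6 libraries, without covariates, two-sided. A positive log2 fold change means higher in siPRDX3, on the log2(value + 1) scale; for a miRNA at 0 in some libraries it depends on the added 1 and on the step, and it is no bound. A miRNA was tested where at least 3 libraries reached the CPM that 10 reads make in a library of median size, which is 113, with at least 15 reads in all. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For 27 lists of miRNAs fixed beforehand, those with at least 3 tested members entered limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Group differences of single measures were tested by exact permutation of the 6 libraries, two-sided, for which the smallest possible p is 0.1. They form a family of 12 measures and another of 24 list shares. Of the 12, the number of reads and the 5 shares of named miRNAs or lists were added after the data were seen.

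The miRNAs named in the text were chosen by a rule fixed beforehand. It takes miRNAs past the threshold with separated groups, filled up to 5 in each direction with those of lowest unadjusted p. It adds the 10 most abundant miRNAs, and up to 3 members of each list by abundance. Any other miRNA named was chosen after its values were seen. Hairpin positions were taken from GENCODE v29 on GRCh38, in which 680 of the 686 entries with reads matched a hairpin gene by name. These are positions of hairpin genes, and they were not used to count reads. Where mature sequences derive from several hairpins or nearly identical family members, or from hairpins that overlap on opposite strands, the way reads were divided between entries is unknown and the entries are uncertain.

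Alternatives covered the scaling, the filter, the pseudocount, limma-voom, the replicate number as a block, the library composition, thinning to the smallest library and leaving out each library. Alternatives added after the data were seen left out siCTL 1 and siCTL 2 together, left out opposite-strand partners, used limma-voom with the library sizes implied by the authors' scaling, used quasi-Poisson regression on the recovered reads, compared shares of reads for separated groups, and thinned the libraries without miR-4451. The test was tried on simulated data with 80 miRNAs, of which 20 were changed, in 50 datasets. With the spread of these libraries it recovered 0.4% of 4-fold, 8.1% of 16-fold and 27.2% of 64-fold changes. With 0.25 times that spread it recovered 40.2%, 82.6% and 97.1%. Figures were drawn with matplotlib 3.10.9.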

Results

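Mature miRNAs were profiled in exosomes of HCT116 colorectal carcinoma cells transfected with a control siRNA (siCTL, n = 3 libraries) or with an siRNA against PRDX3 (siPRDX3, n = 3). PRDX3 encodes a mitochondrial peroxiredoxin that reduces hydrogen peroxide. The comparison addressed which exosomal miRNAs differ when PRDX3 is depleted. PRDX3 mRNA is not measured by a miRNA assay, so neither the knockdown nor the group labels could be checked in these data. The libraries held between 40149 and 230947 miRNA reads, a shallow depth for 2588 entries. Of these entries, 686 had at least 1 read in any library, 1902 were at 0 in all, and 80 had enough reads to be tested. The tested miRNAs took between 92.4% and 99.3% of the reads of a library.

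The exosomal reads were dominated by a few miRNAs. On average the most abundant entry was miR-4451, whose hairpin lies in an intron of ARHGAP24 on chromosome 4 (85722468 to 85722533, plus strand). It took 47.6% ± 30.3 of reads in siCTL and 33.2% ± 18.9 in siPRDX3 (mean ± SD, n = 3 each; exact permutation p = 0.4, adjusted p = 0.8 over 12 measures). Its share ran from 11.8% in siPRDX3 1 (95% Clopper-Pearson interval 11.7 to 11.96) to 76.9% in siCTL 2 (76.6 to 77.2). In siPRDX3 1 let-7b-5p took more, 13.5% of reads. The let-7 family, abundant in differentiated cells, took 15.5% ± 6.29 of reads in siCTL and 19.3% ± 7.07 in siPRDX3 (SD, n = 3 each; exact permutation p = 0.6). Within it let-7b-5p and let-7a-5p led, with log2 levels of 16.44 ± 0.29 and 15.63 ± 0.40 in siCTL and of 15.73 ± 0.69 and 14.80 ± 0.86 in siPRDX3 (SD, n = 3). miR-122-5p, the main miRNA of hepatocytes, ranked among the 10 most abundant entries with 1874, 48 and 6670 reads in siCTL 1, 2 and 3 and 5636, 9313 and 2371 in siPRDX3 1, 2 and 3. The remaining members of the 10 most abundant were miR-7704, miR-486-5p, miR-423-5p, miR-3184-3p, let-7f-5p and miR-10a-5p. None of the 10 passed the test, with adjusted p-values from limma between 0.397 for miR-486-5p and 0.776 for let-7f-5p.

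**Figure D1:**
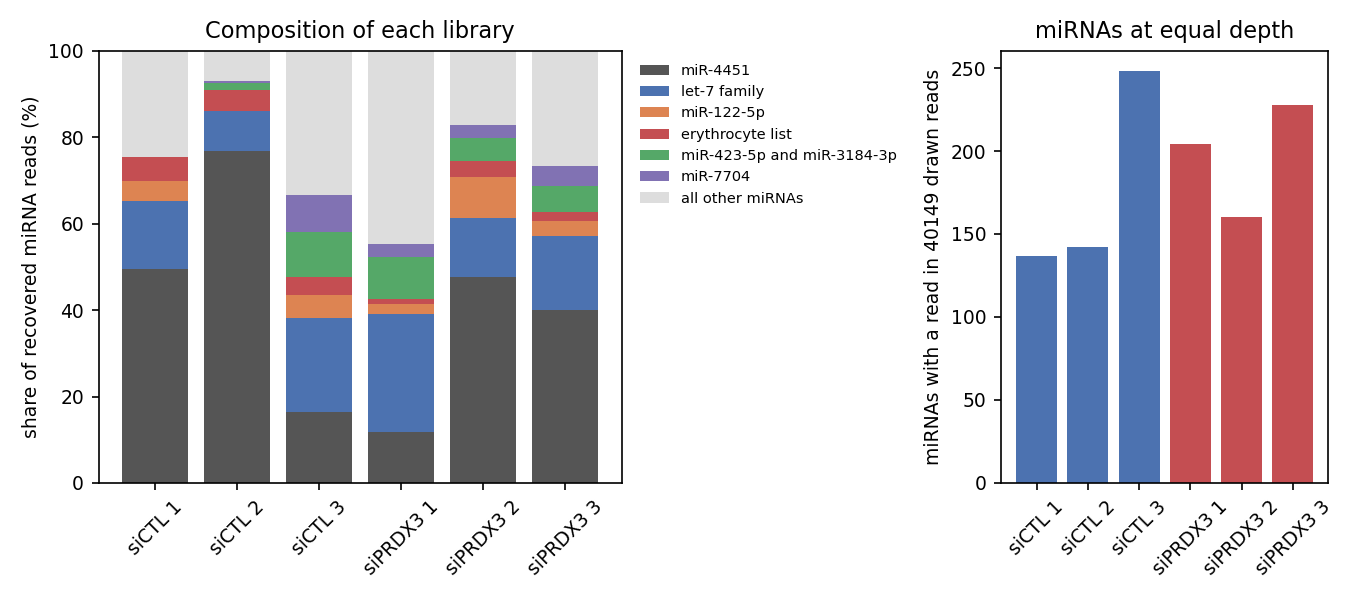
Left, share of recovered miRNA reads (%) taken by named miRNAs and lists in each library, stacked to 100%. Right, number of miRNAs with at least 1 read after every library was thinned to 40149 reads, with siCTL in blue and siPRDX3 in red. Each bar is 1 library, and miR-4451 takes 76.9% of siCTL 2 but 11.8% of siPRDX3 1.

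Several abundant miRNAs were nearly or fully missing from siCTL 1 or siCTL 2 while the other 4 libraries held them in quantity. miR-7704, whose hairpin overlaps an exon of HOXD1 on chromosome 2 (176188843 to 176188901, plus strand), had 0 reads in siCTL 1 and 442 in siCTL 2, against 10613 in siCTL 3 and 2908 to 6973 in siPRDX3. miR-10a-5p, encoded within the HOXB cluster on chromosome 17 (48579838 to 48579947, minus strand), had 0 reads in siCTL 2 and 1407 in siCTL 1, against 4537 in siCTL 3 and 1183 to 9718 in siPRDX3. Counts of 0 allow shares of up to 0.00747% in siCTL 1 and 0.00371% in siCTL 2. Of the 80 tested miRNAs, 30 had no read in siCTL 1 and 23 had none in siCTL 2. The number was 0 in siCTL 3 and 1, 8 and 1 in siPRDX3 1, 2 and 3. A tested miRNA needed enough reads in at least 3 libraries, so one confined to siCTL 1 and siCTL 2 could not enter. Part of the imbalance was therefore built in, also for principal components of these miRNAs. Over all entries at equal depth without miR-4451, siCTL 2 held 189 miRNAs and siCTL 1 held 130.6. The siPRDX3 libraries held 145.9 to 208.8 there. The first principal component of the tested log2 levels, with 65.7% of the variance, placed siCTL 1 and siCTL 2 on one side at −39.9 and −29.2. The other 4 libraries lay between 3.98 and 24.1. Across miRNAs, which are not independent replicates, siCTL 3 correlated with the siPRDX3 libraries at Pearson's r of 0.58 to 0.77. With siCTL 1 and siCTL 2 it correlated at 0.22 and 0.33, and these 2 correlated with each other at 0.62. The division was not sharp, since siPRDX3 2 correlated with siCTL 1 and siCTL 2 at 0.41 and 0.43. With siCTL 3, siPRDX3 1 and siPRDX3 3 it correlated at 0.58, 0.59 and 0.65.

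**Figure D2:**
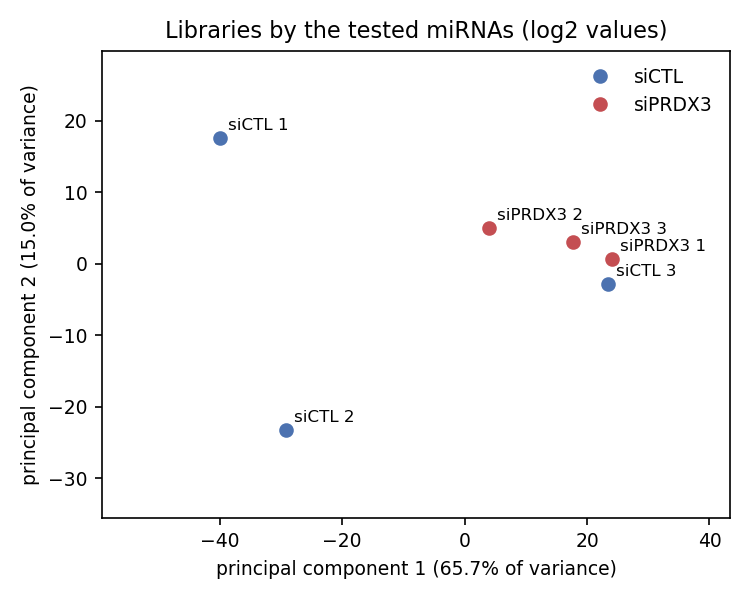
Principal components 1 and 2 of the log2 levels of the 80 tested miRNAs, in units of log2 level, for the siCTL libraries (blue) and the siPRDX3 libraries (red). Each point is 1 library. siCTL 3, at 23.4 on component 1, lies beside siPRDX3 1 at 24.1, while siCTL 1 and siCTL 2 lie at −39.9 and −29.2.

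Against this spread within siCTL, no miRNA differed between the groups past the adjusted threshold. The miRNAs with the lowest p-values on the higher side were miR-1260b and miR-1260a, near-identical entries from separate hairpins on chromosomes 11 (96341438 to 96341526) and 14 (77266218 to 77266290). miR-1260b had 0, 0 and 5 reads in siCTL 1, 2 and 3 and 777, 330 and 204 in siPRDX3 1, 2 and 3, a log2 fold change of 9.15 with SE 2.14 (limma, adjusted p = 0.184). miR-1260a had 0, 0 and 4 reads against 121, 341 and 217 (log2 fold change 8.40, SE 2.24, limma adjusted p = 0.184). Together they made up 0.0024% ± 0.0042 of siCTL reads and 0.560% ± 0.156 of siPRDX3 reads (SD, n = 3 each). This sum was chosen after the values were seen, for the low p-values of both entries, so no separate p is given for it. miR-197-3p, within GNAI3 on chromosome 1 (109598893 to 109598967), had 0, 0 and 11 reads against 258, 44 and 165 (log2 fold change 7.17, limma adjusted p = 0.397). miR-574-5p, in an intron of FAM114A1 on chromosome 4 (38868032 to 38868127), had 0, 19 and 10 reads against 698, 380 and 151 (5.83, adjusted p = 0.491). miR-941, with 5 hairpin copies in introns of DNAJC5 on chromosome 20, had 0, 0 and 4 reads against 64, 43 and 10 (5.63, adjusted p = 0.491).

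On the lower side, miR-4695-3p had 1202, 66 and 259 reads in siCTL and 10, 3 and 11 in siPRDX3 (log2 fold change −6.87, SE 1.81, limma adjusted p = 0.184). Its hairpin lies on chromosome 1 (18883202 to 18883275, minus strand), in an intron of the same gene as that of miR-1290 (18897071 to 18897148). miR-1290, whose sequence resembles U2 small nuclear RNA, also lay higher in every siCTL library than in any siPRDX3 library on the authors' scaling (−1.63, SE 1.006, adjusted p = 0.538). As shares of reads its libraries overlapped (5.44%, 1.02% and 1.18% in siCTL, 1.54%, 1.45% and 0.713% in siPRDX3), and its fold change was −0.68 under library totals. The erythroid miRNAs miR-486-5p (chromosome 8, 41660441 to 41660508, within ANK1) and miR-451a (chromosome 17, 28861369 to 28861440) came next. miR-486-5p had a log2 level of 15.19 ± 0.44 in siCTL and 12.94 ± 0.70 in siPRDX3 (SD, n = 3), a fold change of −2.25 with SE 0.80 (limma adjusted p = 0.397). miR-451a stood at 14.002 ± 0.82 and 11.87 ± 1.28 (−2.13, SE 1.09, limma adjusted p = 0.491). miR-6815-5p, in an intron of COL18A1, had few reads (22, 31 and 5 against 0, 1 and 11), and miR-4451 had a log2 fold change of −1.44 (limma adjusted p = 0.504). The size for miR-4451 depended on the scaling. It was −0.49 under library totals, −0.36 under limma-voom with TMM and −2.18 with upper-quartile factors.

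**Figure D3:**
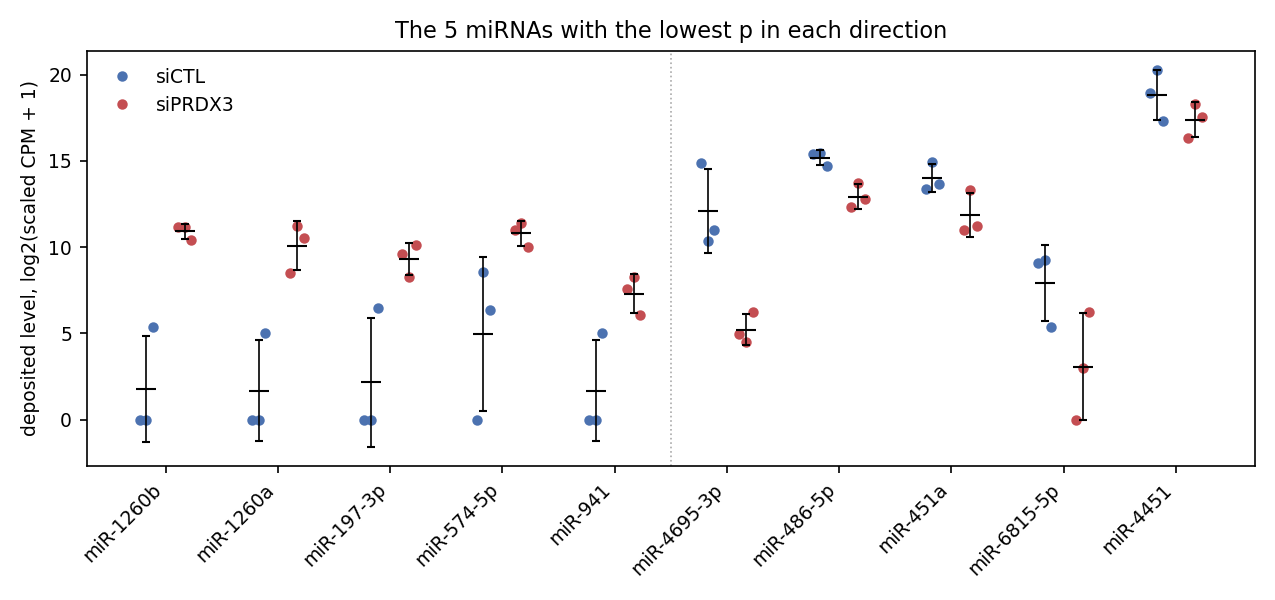
Deposited log2(scaled CPM + 1) levels of the 5 miRNAs of lowest p in each direction, 1 point per library, for siCTL (blue) and siPRDX3 (red). Horizontal bars are means and whiskers are SD (n = 3). The siCTL points of miR-1260a and miR-1260b at 0 are siCTL 1 and siCTL 2, and none of the 10 miRNAs passed the adjusted threshold.

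By limma, 0 of the 80 miRNAs passed an adjusted p of 0.05, and the smallest adjusted p was 0.184. At an unadjusted p under 0.05 there were 6, of which 4 were higher and 2 lower in siPRDX3, where 4 would be expected by chance. All 6 had at least a 2-fold change. The miRNAs are not independent, so such counts vary widely around their chance values. Other groupings of the 6 libraries, 3 against 3, gave 0 to 23 miRNAs at an unadjusted p under 0.05. The groups did not overlap for 13 miRNAs (6 with siPRDX3 above, 7 with siCTL above), which is 16.2% against the 10% that chance gives for 3 against 3. As shares of reads, a comparison chosen after seeing the data, they did not overlap for 12 (10 with siPRDX3 above, 2 with siCTL above), of which 8 were among the 13. limma-voom gave 0 miRNAs with TMM scaling (12 at an unadjusted p under 0.05) and 0 with the authors' implied sizes (8), and quasi-Poisson regression gave 0 (5). Fitted fold changes lay above 0 for 51 of the tested miRNAs and below 0 for 29, with a median of 1.72 and a median SE of 2.40. The share above 0 was 63.7%, and it was 73.8% under library totals, 75% under limma-voom with TMM and 56.2% with upper-quartile factors. Quasi-Poisson regression gave 40%, with a median of −0.44. The count of calls rested on siCTL 3. Without that library 20 miRNAs passed (19 higher, 1 lower; 34 at an unadjusted p under 0.05). They included miR-1260b (adjusted p = 0.00267, against 0.0757 to 0.797 in its other settings), miR-1260a, miR-197-3p and miR-4695-3p. In contrast, without siCTL 1 and siCTL 2 together 0 passed (3 unadjusted), the median fold change was −1.15 and 21.2% of the fold changes lay above 0.

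Of the 27 fixed lists, 24 had reads and 8 had at least 3 tested members, and 1 passed camera with the preset correlation. That list was the erythrocyte miRNAs, lower in siPRDX3 (adjusted p = 0.0148). The call was lost with an estimated correlation of 0.507 (adjusted p = 0.653) and by fry (0.102), as well as without siCTL 2 (0.0588), siCTL 3 (0.0951) or siPRDX3 1 (0.061). Its 3 tested members, miR-486-5p, miR-486-3p and miR-451a, each lay higher in every siCTL library than in any siPRDX3 library on the authors' scaling, with fold changes of −2.25, −1.99 and −2.13, and 0 passed over all miRNAs or adjusted over the list alone. As shares of reads the groups overlapped for miR-486-3p and miR-451a. Under library totals the fold changes were −1.30, −1.04 and −1.18, and the list had a camera adjusted p of 0.0242. camera ranks a list against the other miRNAs, and the median over all tested miRNAs rose too, from 1.72 to 2.57. A scaling that moves nearly all miRNAs together can hardly change the camera result, so this p is no added support. The list took 4.84% ± 0.72 of reads in siCTL and 2.23% ± 1.23 in siPRDX3 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, adjusted p = 1 over 24 lists). Red cells are not part of a cell line culture, and these miRNAs are also abundant in serum. The liver list, carried by miR-122-5p, took 3.36% ± 2.88 and 5.14% ± 3.92 (exact permutation p = 0.6). Leukocyte and platelet miRNAs took 0.0060% ± 0.0094 and 0.137% ± 0.233, the latter from 287 reads of miR-146a-5p in siPRDX3 3 and 11 of miR-142-5p in siPRDX3 1.

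Among the other tested lists, 0 passed and 0 members passed over all miRNAs. The let-7 family had 4 of 8 tested members above 0 and 4 below (camera adjusted p = 0.555). Its median fold change was −0.01, against 1.72 over all tested miRNAs. camera, which ranks a list against the other miRNAs, pointed downward and fry upward. The directions of let-7a-5p, let-7b-5p and let-7f-5p also depended on the scaling. The group of the miR-10, miR-99, miR-100 and miR-125 families had 4 of 5 above 0 (camera adjusted p = 0.554), led by miR-100-5p, with 0, 1 and 1574 reads in siCTL and 7228, 321 and 2284 in siPRDX3 (log2 fold change 7.15, SE 3.36, limma adjusted p = 0.491). The group listed as enriched in exosomes had 4 of 8 above 0 (adjusted p = 0.554). In it miR-320a had 1, 32 and 2711 reads against 8881, 2222 and 997 (4.31, SE 2.38, limma adjusted p = 0.502), while miR-1290, miR-486-5p and miR-451a lay below 0, and the median was 1.67. The list of entries that overlap other RNAs had 6 of 9 above 0 (camera adjusted p = 0.554). Of its members 2, miR-1260a and miR-1260b, passed when adjusted over the list alone, and 0 passed over all miRNAs. In the same list miR-1246, which resembles U2 small nuclear RNA, had a fold change of −0.15 whose sign changed with the scaling, and miR-4508 stood at 1.70 with SE 3.61. Colorectal tumour miRNAs (3 of 4 above 0, adjusted p = 0.878) had a median of 0.28. They included miR-182-5p with 2, 1 and 1727 reads against 2822, 77 and 196. miR-21-5p, raised in many carcinomas, had only 37, 55 and 133 reads against 559, 92 and 23 (−0.89, SE 1.53, limma adjusted p = 0.737), and its sign changed under library totals and limma-voom with TMM, but not under limma-voom with the authors' implied sizes. The list described in serum exosomes of colorectal cancer had 0 of 3 above 0 (camera adjusted p = 0.554). Its tested members also belong to lists above. These are let-7a-5p of the let-7 family, miR-21-5p of the colorectal tumour list and miR-1246 of the entries that overlap other RNAs. The list with miR-148a-3p (−0.999), miR-222-3p (5.61) and miR-221-3p (2.10) had a camera adjusted p of 0.989.

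Lists close to the targeted gene or to its known functions were hardly covered. The 3 detected miRNAs described as targeting PRDX3, namely miR-23a-3p, miR-23b-3p and miR-26a-5p, were too sparse to test. Their list took 0.0080% ± 0.0118 of siCTL reads and 0.279% ± 0.293 of siPRDX3 reads (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 1), of which 1293 reads of miR-23a-3p came from siPRDX3 1. Of 11 mitochondria-associated miRNAs 1 was tested, miR-378a-3p, with 0, 816 and 44 reads against 67, 0 and 5 (log2 fold change −3.23, SE 3.89, limma adjusted p = 0.608). Hypoxia and redox miRNAs took 0.275% ± 0.333 and 0.258% ± 0.142, with miR-21-5p and miR-200c-3p as the tested members. miR-200c-3p, an epithelial miRNA that represses ZEB1 and ZEB2, had 0, 0 and 450 reads against 253, 1 and 190 (3.69, SE 3.85, limma adjusted p = 0.59). The p53-induced miRNAs reached 0.218% ± 0.368 in siCTL and 0.0054% ± 0.0046 in siPRDX3 (exact permutation p = 0.7), with 580 reads of miR-215-5p and 220 of miR-192-5p in siCTL 3. In the miR-17~92 and related clusters, miR-92a-3p had 78, 31 and 331 reads against 943, 262 and 158 (0.26, SE 1.33), and miR-25-3p had 0, 0 and 263 against 887, 446 and 22 (6.39, SE 3.34, limma adjusted p = 0.491). miR-128-3p, the tested member of the neuronal list, stood at 3.66 with SE 2.43, and miR-432-5p of the imprinted cluster on chromosome 14 at 4.55 with SE 3.57.

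The fold changes of miR-100-5p, miR-320a, miR-182-5p, miR-200c-3p, miR-25-3p, miR-222-3p, miR-221-3p and miR-432-5p lay above 0 in the comparison of all 6 libraries and below 0 without siCTL 1 and siCTL 2. The miR-23/27/24 clusters took 0.0634% ± 0.108 and 0.255% ± 0.418, the miR-30 family 0.0214% ± 0.0307 and 0.0494% ± 0.0606, and the miR-15/16 family 0.00080% ± 0.0014 and 0.0388% ± 0.0672. Markers of other cell types were sparse as well. Fibroblast and smooth muscle miRNAs reached 0.00053% ± 0.00093 and 0.0038% ± 0.0036, endothelial ones 0.0022% ± 0.0020 and 0.0734% ± 0.125, striated muscle ones 0.0517% ± 0.0889 and 0.00043% ± 0.00075, and neuronal ones 0.0072% ± 0.0105 and 0.0521% ± 0.0603 (siCTL then siPRDX3, SD, n = 3 each). No exact permutation test of these shares gave a p below 0.3. The miR-29 family, the miR-371 and miR-302 clusters and the primate cluster on chromosome 19 had 0 of 644116 reads, which allows a share of up to 0.000466%.

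Library diversity did not differ detectably between the groups. siCTL libraries held 137, 190 and 356 miRNAs with at least 1 read (227.7 ± 114, SD, n = 3) and siPRDX3 libraries 334, 215 and 272 (273.7 ± 59.5), with an exact permutation p of 0.6. At equal depth the numbers were 137, 142 and 248 against 204, 160 and 228 (exact permutation p = 0.7). With miR-4451 left out and every library thinned to 18713 reads, a setting chosen after seeing the data, they were 130.6, 189 and 197.4 against 176.3, 145.9 and 208.8 (means of 100 draws, exact permutation p = 0.9). The 10 most abundant miRNAs took 84.1% ± 14.4 of reads in siCTL and 73.5% ± 10.4 in siPRDX3 (SD, n = 3 each; exact permutation p = 0.3). Over the 12 measures the adjusted p was 0.8 for the number detected and for the share of the 10 most abundant, and 0.84 at equal depth. The setting without miR-4451 is not among the 12, and its p is unadjusted.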

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

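The count of 0 miRNAs past the threshold held under every alternative of scaling, filter, pseudocount, tool and composition, and under the added ones; only the leave-one-out settings moved it, from 0 to 20 (without siCTL 3). Of those 20 miRNAs, 10 had no read in siCTL 1 and siCTL 2. The settings without siCTL 1 and siCTL 2 together, without opposite-strand partners, with implied sizes and with quasi-Poisson regression were chosen after seeing the data; the first leaves 1 control, which is assumed to vary like siPRDX3. The planned DESeq2 Wald test and the planned edgeR tests were not run, because the plan set limma for values that are not raw counts. They could have been tried on the recovered reads, which limma-voom and quasi-Poisson regression used. With the replicate number as a block, 0 miRNAs (7 unadjusted) and 0 lists passed (erythrocyte list 0.0615). The labels do not say whether the numbers pair the samples. Same-numbered libraries deviated from their group means with correlations of −0.238, 0.177 and 0.140. Differently numbered ones ran from −0.360 (siCTL 3 with siPRDX3 2) to 0.329 (siCTL 3 with siPRDX3 1). So few libraries cannot decide whether a day or batch was shared. Relative to the authors' scaling, library totals raised the siPRDX3 libraries against the siCTL libraries by a mean of 0.95 (log2), and median-of-ratios factors by 0.40, with other amounts for single miRNAs.

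Without the 10 most abundant miRNAs 0 of 6 lists passed, but the erythrocyte list was not tested there, since leaving out miR-486-5p left it 2 tested members. The count of 1 list became 0 with an estimated correlation (erythrocyte adjusted p = 0.653), with fry (0.102) and without siCTL 1 and siCTL 2 together (0.62, with fewer samples). In that last setting the members stayed lower in siPRDX3, at −1.75 for miR-486-5p, −2.41 for miR-486-3p and −1.80 for miR-451a. In the main comparison these were −2.25, −1.99 and −2.13. The median over all tested miRNAs moved from 1.72 to −1.15. camera ranks a list against the other miRNAs, so the lost call cannot be put down to the number of samples alone. Leaving out 1 library gave 0 to 1 lists and erythrocyte adjusted p-values of 0.00239 to 0.0951. The group differences in miRNAs detected (0.667 to 110.2 without 1 library) and in the share of the 10 most abundant (−18.8 to −5.00 points) kept their direction. With miR-4451 left out before thinning, chosen after seeing the data, the difference in miRNAs detected was 4.64.

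Of 36 named miRNAs, 12 kept their sign under all 15 settings, miR-1260a, miR-1260b and miR-4695-3p among them. The groups of miR-1260a, miR-1260b and miR-4695-3p did not overlap. Leaving out libraries, another pseudocount or the replicate block could therefore not reverse them. They were also named for low p-values in these data, so a kept sign is no added support. The log2 fold change of miR-1260b ran from 5.58 to 11.37. Without siCTL 1 and siCTL 2, 17 reversed: miR-4451 (0.073), miR-122-5p (−1.03), miR-7704 (−1.99), miR-423-5p (−1.38), miR-3184-3p (−1.31), let-7f-5p (−0.699), miR-10a-5p (−1.31), miR-92a-3p (−0.578), miR-25-3p (−0.965), miR-200c-3p (−4.18), miR-182-5p (−2.92), miR-320a (−0.620), miR-100-5p (−0.466), miR-222-3p (−1.93), miR-221-3p (−5.07), miR-432-5p (−2.05) and miR-4508 (−5.71). Library totals reversed let-7b-5p (0.243), let-7a-5p (0.127), miR-21-5p (0.056) and miR-1246 (0.802). limma-voom with TMM reversed let-7b-5p (0.410), let-7a-5p (0.322), miR-21-5p (0.305), miR-1246 (1.20) and miR-148a-3p (0.062). Upper-quartile factors reversed let-7f-5p (−0.243) and miR-92a-3p (−0.475), median-of-ratios factors miR-1246 (0.253), and a pseudocount of 0.1 miR-10b-5p (0.234). Over the settings that leave out 1 library, the ranges that crossed 0 were miR-122-5p (−0.94 to 1.96), miR-7704 (−0.35 to 7.83), miR-423-5p (−0.42 to 3.02), miR-3184-3p (−0.33 to 3.27), let-7f-5p (−0.40 to 1.09), miR-10a-5p (−1.29 to 6.28), miR-92a-3p (−0.36 to 0.68), miR-21-5p (−1.69 to 0.022), miR-378a-3p (−6.97 to 0.023), miR-1246 (−1.11 to 0.48), miR-10b-5p (−5.44 to 1.83), miR-221-3p (−0.21 to 5.68) and miR-4508 (−1.49 to 5.40). The cause was not tested.

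At this depth and spread, the simulated test recovered 8.1% of 16-fold and 27.2% of 64-fold changes. The count of 0 therefore says little about differences of these sizes or smaller ones. The simulation gave both groups the same spread and let miRNAs vary independently, whereas siCTL 1 and siCTL 2 differed jointly in many miRNAs here.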

Other observations

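All tests in this part were chosen after the results were seen.

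Many entries with too few libraries to test were abundant in a single one. Of 606 untested entries, 351 had reads in 1 library only, and 105 had at least 10 reads in exactly 1. At least 50 reads in 1 library and at most 1 read in each of the other 5 were found for 32 entries: 16 in siPRDX3 1, 8 in siCTL 3, 5 in siCTL 2, 2 in siPRDX3 3, 1 in siPRDX3 2 and 0 in siCTL 1. The most abundant of these were miR-7706 with 1169 reads in siPRDX3 1, miR-3679-5p with 722 in siPRDX3 1 and miR-4713-5p with 403 in siCTL 2. Also among the 32 were miR-103a-3p with 141 reads and miR-15b-5p with 269 in siPRDX3 1, and miR-146a-5p with 287 in siPRDX3 3. miR-126-3p, an endothelial miRNA, had 154 reads in siPRDX3 3 and at most 5 in any other library. miR-16-5p, among the most abundant miRNAs of most human cells, had 2 reads over the 6 libraries. These miRNAs were picked after their values were seen. The ratio of the liver list's share to the erythrocyte list's share was 0.837, 0.0124 and 1.29 in siCTL 1, 2 and 3, and 2.24, 2.72 and 1.63 in siPRDX3 1, 2 and 3.

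The first pattern is that siCTL 1 and siCTL 2 stand apart from the other 4 libraries. Fewer reads are argued against: 16 tested miRNAs had no read in siCTL 1 or siCTL 2 although the lowest share among the other 4 libraries predicted at least 10, such as 1208 reads of miR-7704 in siCTL 1 and 1355 of miR-10a-5p in siCTL 2. miR-4451 taking most of the reads is argued against as the whole source, since 13 such miRNAs remained with miR-4451 left out of every library. siCTL 3 carries the same siRNA by its title, and no biological explanation was tested. The amount of RNA behind each library, a batch and the label of siCTL 3 were not tested and stay open, since the labels give none of them and PRDX3 is not measured.

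The second pattern is that miR-1260a and miR-1260b lay near 0 in siCTL, with 9 reads in all, and were present in every siPRDX3 library, with 1990. Fewer reads in siCTL are argued against: at the lowest siPRDX3 share, 0.389%, at least 156 reads were expected in each siCTL library. The absence of many tested miRNAs from siCTL 1 and siCTL 2 does not account for siCTL 3. That library held the most miRNAs, and both entries together had a share of 0.0072% in it (95% Clopper-Pearson interval 0.0033 to 0.0137). Both entries resemble fragments of transfer RNA. Whether fragments of other RNAs rose in general in siPRDX3 is not decided, since both entries were picked for their low p-values. In the 7 other tested members of that list the mean share of reads changed by a median log2 ratio of 0.767 (SD 1.86 between members). These ratios ran from −1.83 for miR-4508 to 3.43 for miR-4488. For miR-1260a and miR-1260b, the lowest siPRDX3 share lay log2 4.83 above the highest upper 95% limit of their share in a siCTL library. All other members of the list, tested or not, took 3.67% ± 1.95 of siCTL reads and 2.70% ± 0.77 of siPRDX3 reads. A rise of transfer RNA fragments alone, a batch that follows the groups and an effect of the PRDX3 siRNA stay open, and none was tested.

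The third pattern is that miR-423-5p and miR-3184-3p, whose hairpins overlap on opposite strands of chromosome 17 (30117079 to 30117172 and 30117086 to 30117160), had nearly equal reads in every library, 23125 and 23221 in all. Reads of 1 locus divided at random between both entries may be the source: miR-3184-3p took 48.95% ± 2.72 of the reads of the pair (SD, 6 libraries; 43.75% to 51.58%). Other opposite-strand pairs with at least 20 reads in a library were also compared. The other arms of the same hairpins, miR-423-3p and miR-3184-5p, were divided unevenly in each of 4 libraries (the second took 36.1% ± 6.10, 31.8% to 45.1%). So were miR-122-5p and miR-3591-3p in all 6 (18.7% ± 12.6, 5.16% to 40.7%). Only hairpin positions were available, so these pairs cannot decide the source for miR-423-5p and miR-3184-3p, which stays open. The share of the second varied from 21.2% to 80.4% for miR-7-5p and miR-3529-3p, and in single libraries it was 51.6% for miR-203a-3p and miR-203b-5p, 44.9% for miR-103a-3p and miR-103b, and 98.9% for miR-550b-3p and miR-550a-5p. No biological explanation was tested, and if reads were so divided, the values printed for miR-423-5p and miR-3184-3p are not independent of each other.

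With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. For the count of miRNAs, 10 of the 10 splits gave at least the real count of 0, an outcome that a count of 0 fixes and that tests nothing. The highest other split gave 10, with siCTL 1, siCTL 2 and siPRDX3 2 against the rest. Like the real groups, which gave 0, that split puts siCTL 1 and siCTL 2 on one side, as the first principal component does. It differs from the real groups in holding siPRDX3 2 in place of siCTL 3. Of the other libraries, siPRDX3 2 lay nearest to siCTL 1 and siCTL 2 on that component, at 3.98. For the count of lists, 1 of the 10 splits gave as many as the real 1, and the highest other gave 0.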
